A study of Drosophila melanogaster with 17 samples.

How the data were processed

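The deposited tables of 17 libraries were used, with unique molecular identifier (UMI) counts per gene and barcode that the authors had made before deposition. The submitters' processing notes name bcl2fastq, STAR 2.5.2a and the BDGP6 build. The program that counted, the annotation, the barcode threshold and the handling of strand are not given in the sources used here. Reads shared between close copies (the Hsp70, Mst57, Jon, maltase, metallothionein and histone families), and between overlapping or antisense genes, therefore cannot be separated. Genes numbered 16284, of which 12213 matched the reference annotation (BDGP6.54) by symbol, 3922 by synonym and 149 not at all. The files hold no coordinates, and those printed are of BDGP6.54.

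Barcodes with at least 200 UMIs and 100 genes were kept (199870 of 200000). Counts were scaled to 10000 per barcode and log-transformed. The 2000 most variable genes, 50 principal components and 15 neighbours gave 29 Leiden clusters at resolution 1 (scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, Python 3.11.15). A cluster took the name of the marker list with most genes among its 10 leading genes, if no other list had as many. At least 3 markers of the list had to be higher by 2-fold or more, and their mean log2 fold had to reach 1.5. By this 13 clusters gave 11 classes, while 16 stayed unnamed, among them 2 clusters of mixed content that were split further. The thresholds and that split were chosen after seeing the data. Scrublet's own threshold marked 10 barcodes (0.005%) and was not used. No barcodes were removed as doublets.

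Whole-library sums were compared with edgeR 4.0.16 (quasi-likelihood, TMM factors, R 4.3.3) on all 3 groups in 1 fit, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 0.328. Gene lists were tested with camera of limma 3.58.1, with an inter-gene correlation of 0.01 and again with the correlation estimated, and with fry. Within classes, counts were summed per library where it had at least 20 cells of the class, and fitted the same way. DESeq2 1.42.0 was the second method. Shares of barcodes per library were compared by an exact two-sided permutation test. Where the leading genes of a class differed by age, clusters were made again without 7775 genes called by age.

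The genes tested, the 30 lists, the tests and the alternatives planned were fixed before the data were examined. Largest changes were named among the top 12 genes per direction by log2 fold change with a mean of at least 50 CPM, and list members among the top 3 with at least 10 CPM. Genes with no count in a group are given as at least N-fold, against a floor of 3 counts over the group, and genes with 1 to 3 counts as levels only. On simulated data with known changes in 200 of 12381 genes, the age fit found 78% and 82% of 2-fold changes up and down and 96% and 96% of 4-fold changes, with 7.85% of calls false. The sex fit found 34% and 38%, 90% and 82%, with 3.17% false. The changed genes had a mean of at least 10 CPM, and the simulated libraries varied independently. Far fewer genes were changed than were called in the data, so these rates need not hold for the real fits. Other tools were numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.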

Results

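Single-cell RNA libraries were made by Microwell-seq, in which single cells and barcoded beads share microwells, from whole w1118 *Drosophila melanogaster*, a white-eyed laboratory strain. Flies were taken 11 or 16 days after egg laying. The labels give 6 libraries of females at day 11, 2 of males at day 11 and 9 of females at day 16. Each library was summed over its barcodes, and its total was 10502617 to 31770786 UMIs (unique molecular identifiers) in the day 11 female libraries. The totals were 8455391 and 14526161 in the male libraries and 19023148 to 30138715 in the day 16 libraries. The files hold 200000 barcodes, against more than 270000 cells that the series text states for a population not described further. The labels do not say whether the libraries of a group came from different flies, so the p-values measure only the spread between these libraries, which may be technical. At day 11, libraries 1 and 2, and 5 and 6, were each other's closest. So were libraries 1 and 2, 3 and 4, 5 and 6, and 9 and 10 at day 16. The number of independent samples is thus not known. Levels are CPM, edgeR's library-scaled counts with TMM factors unless said otherwise. They are given as mean ± SD over libraries, with n = 6 (day 11 female), n = 2 (day 11 male) and n = 9 (day 16 female). Log2 fold changes carry their standard errors.

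The labelled sex was compared with transcripts of known sex bias. roX1, a non-coding RNA of the male dosage compensation complex, stood at 945 and 376 CPM of the library total in the libraries labelled male, replicates 7 and 8. Of the libraries labelled female at day 11, replicates 1 and 2 held 1.58 to 2.42 CPM and replicates 3 to 6 held 55.9 to 74.6 CPM. At day 16 it stood at 27.6 to 186 CPM. The summed accessory gland and ejaculatory protein transcripts, made in male reproductive glands, took 255 to 319 CPM in day 11 replicates 1 and 2, 1413 to 2430 CPM in replicates 3 to 6, and 92.4 to 234 CPM at day 16. Yp1, a yolk protein gene of the female fat body and ovary, had 1510 to 3660 CPM in the day 11 female libraries. It had 3.67 CPM in the library labelled male, replicate 7, and 1982 CPM in the library labelled male, replicate 8. Replicate 8 thus carried transcripts of both sexes, and the directions by sex below rest on the labels.

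**Figure D1:**
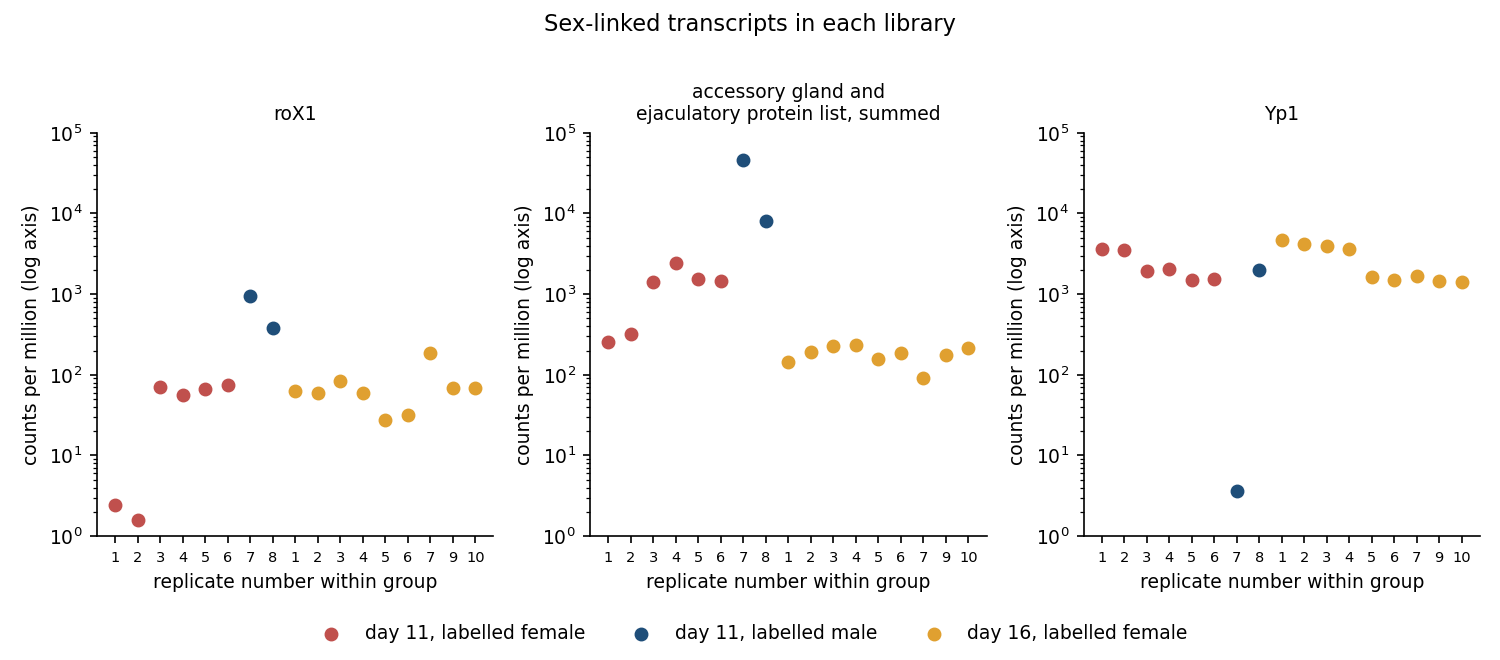
CPM of library total (log axis) of roX1, of the summed accessory gland and ejaculatory protein list and of Yp1, with 1 point per library, by replicate number within group. The library labelled male, replicate 7, has 3.67 CPM of Yp1, against 1982 CPM in replicate 8, and day 11 female replicates 3 to 6 hold 55.9 to 74.6 CPM of roX1.

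The first comparison asks how the female transcriptome differed between day 16 and day 11. At day 16, Ocho and Tom, members of the Bearded family of small Notch pathway regulators, were higher. Ocho stood at 54.8 ± 36.8 CPM against no count at day 11 (at least 1742-fold higher, against a floor of 3 counts over the group), and Tom at 68.7 ± 40.5 against 0.616 ± 0.168 CPM. The RNA-binding protein gene lin-28 was higher too (59.4 ± 17.8 against 3.61 ± 0.95 CPM). The day 16 libraries also held 4218 barcodes in 3 sub-clusters, against 4 in the day 11 female libraries. These sub-clusters were picked for being all but absent from every day 11 library. Ocho, Tom and CG4440 were among the leading genes of 1 of them. Of 39 patterning genes of the embryo tested, a list besides the 30, 33 were higher and 1 lower, with sna at 8.83 ± 3.60 against 0.0358 ± 0.0417 CPM. Lower at day 16 were Cpr100A, a cuticle protein gene (0.946 ± 0.697 against 310 ± 209 CPM), Lsp2, a larval serum protein gene (0.150 ± 0.090 against 31.2 ± 29.5 CPM), and Mal-A1, a maltase gene (14.9 ± 5.4 against 139 ± 77 CPM). Of 12381 genes tested by edgeR's quasi-likelihood test, 2945 were higher and 3522 lower at day 16, and 777 and 2100 of these by at least 2-fold.

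Without day 11 replicates 3 to 6, the libraries with the male transcripts, 1749 genes were higher and 1664 lower, and 2927 of them had also been called with all libraries. On data simulated for all 17 libraries with known changes, the age fit recovered 78% and 82% of genes raised or lowered 2-fold. Of its calls 7.85% were false. The changed genes had a mean of at least 10 CPM and the simulated libraries varied independently, so these rates need not hold for alike libraries. The fit without replicates 3 to 6 was not simulated.

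Among the largest rises were further CG4440 (89.2 ± 48.6 against 0.617 ± 0.227 CPM) and ImpL1, an ecdysone-inducible gene (log2 fold change 2.93 ± 0.61). ImpE2, at a lower mean of 20.9 ± 20.8 CPM, was higher as well (7.61 ± 0.87). ImpL1 and ImpE2 were among the leading genes of another of the sub-clusters picked as all but absent at day 11. In BDGP6.54 coordinates Ocho lies on chromosome 3L at 14974848 to 14976040 and Tom at 14969344 to 14970306. The 30 gene lists were fixed before the data were examined and tested with camera, and 1 was called higher. This was the hemocyte list, with 10 of 15 genes higher and 1 lower, as many adjusted over the list alone (median log2 fold change 0.64, camera adjusted p = 0.00403, adjusted p = 0.519 with an estimated correlation). Its members include PPO1 and PPO2, prophenoloxidases of crystal cells (log2 fold changes 2.33 ± 0.55 and 2.68 ± 0.42), and Sr-CI, a scavenger receptor gene (1.35 ± 0.15). Without day 11 replicates 3 to 6 the list was no longer called (adjusted p = 0.0672).

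Lists called lower at day 16 numbered 15. The accessory gland and ejaculatory list had 24 of 24 genes lower (24 adjusted over the list alone, median -8.02, camera adjusted p = 5.4e-10, adjusted p = 0.523 with an estimated correlation). Sfp60F, a seminal fluid protein gene, went from 123 ± 103 CPM to no count (at least 9051-fold lower). EbpII, of the ejaculatory bulb, went from 202 ± 174 to 0.0092 ± 0.0182 CPM. Male germline genes fell in 16 of 19 (16 adjusted over the list alone, median -5.09, camera adjusted p = 0.000214, adjusted p = 0.627 with an estimated correlation). This call ended without day 11 replicates 3 to 6 (camera adjusted p = 0.346) and with the replicate block (0.187). Only 5 genes of the list were tested with the block, so that loss need not come from blocking. The medians of both lists stayed at -8.02 and -5.09 with the 4 genes of each at 0 counts in a group set to their bound. Within the day 11 female group these transcripts lay mostly in replicates 3 to 6.

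Larval serum protein and larval fat body genes fell in 7 of 8 (7 adjusted over the list alone, median -7.09, camera adjusted p = 6.86e-05, adjusted p = 0.519 with an estimated correlation). Fbp1 and Fbp2 stood at log2 fold changes of -7.45 ± 0.79 and -7.40 ± 0.74. Within the day 11 female group these transcripts too lay mostly in replicates 3 to 6, with Lsp2 at 22.8 to 71.0 CPM there and at 2.22 to 2.81 CPM in replicates 1 and 2. Cuticle tanning genes fell in 12 of 17 and rose in 1 (12 and 1 adjusted over the list alone, camera adjusted p = 4.51e-05, adjusted p = 0.523 with an estimated correlation). Among them ple, tyrosine hydroxylase, went from 283 ± 170 to 10.3 ± 2.3 CPM and ebony (e), which conjugates dopamine with beta-alanine, from 140 ± 80 to 7.29 ± 2.16 CPM. Cuticle protein genes were 40 of 84 lower and 23 higher (40 and 24 adjusted over the list alone, median -0.59, camera adjusted p = 0.00954, adjusted p = 0.627 with an estimated correlation). It was no longer called without day 11 replicates 3 to 6 (adjusted p = 0.146). Cpr97Ea and Acp1, an adult cuticle protein gene, were among the lower ones (log2 fold changes -7.38 ± 0.66 and -7.26 ± 0.57).

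Digestive hydrolases fell in 32 of 47 (32 adjusted over the list alone, median -1.47, camera adjusted p = 6.78e-08, adjusted p = 0.519 with an estimated correlation). Mal-A7, a maltase gene, stood at -4.52 ± 0.54. Antimicrobial peptides fell in 19 of 23 (19 adjusted over the list alone, median -2.40, camera adjusted p = 1.55e-05, adjusted p = 0.627 with an estimated correlation). Among them were IM3 (31.0 ± 8.7 against 416 ± 260 CPM) and IM4 (11.6 ± 5.5 against 124 ± 56 CPM). That call ended without day 11 replicates 3 to 6 (adjusted p = 0.152). DptB, a diptericin gene, then changed sign (log2 fold change -3.53 ± 0.72 with all libraries and 0.69 without them). Detoxification genes fell in 30 of 69 and rose in 9 (32 and 9 adjusted over the list alone, camera adjusted p = 0.00699, adjusted p = 0.627 with an estimated correlation), but not without replicates 3 to 6 (0.195). Cyp6g1, a cytochrome P450 gene, stood at -2.11 ± 0.26.

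Neuronal genes fell in 17 of 20 and rose in 1 (17 and 1 adjusted over the list alone, median -1.17, camera adjusted p = 4.92e-06, adjusted p = 0.523 with an estimated correlation). Examples are nrv3, a sodium pump subunit (138 ± 20 against 427 ± 112 CPM), noe (307 ± 114 against 926 ± 152 CPM) and Sh, a potassium channel (30.8 ± 3.9 against 84.8 ± 16.9 CPM). Phototransduction genes fell in 9 of 18 (10 adjusted over the list alone, camera adjusted p = 0.0107, adjusted p = 0.627 with an estimated correlation), but not without replicates 3 to 6 (0.361). The photoreceptor membrane protein gene chp lost its own call there (-1.49 ± 0.34 with all libraries, -0.61 without). Odorant-binding proteins fell in 16 of 35 and rose in 4 (16 and 4 adjusted over the list alone, camera adjusted p = 0.0281, adjusted p = 0.627 with an estimated correlation), but not without replicates 3 to 6 (0.356). The lower ones include Obp56g and Obp51a, at 1028 ± 380 and 784 ± 709 CPM in the male libraries of day 11. Obp51a had 2 counts over all day 16 libraries.

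Of energy metabolism, 3 lists were called lower. Nuclear oxidative phosphorylation genes fell in 48 of 80 (53 adjusted over the list alone, median -0.48, camera adjusted p = 8.13e-07, adjusted p = 0.627 with an estimated correlation). ATPsynE stood at -0.88 ± 0.18. Mitochondrially encoded genes fell in 11 of 32 (10 adjusted over the list alone, median -0.62, camera adjusted p = 0.00222, adjusted p = 0.627 with an estimated correlation). The gene mt:ND1 stood at -1.50 ± 0.20. Mitochondrial transcripts took 1.63% to 2.37% of UMIs at day 16 and 2.79% to 4.56% at day 11. Glycolysis genes fell in 11 of 14 (11 adjusted over the list alone, median -0.67, camera adjusted p = 3.01e-05, adjusted p = 0.431 with an estimated correlation). Gapdh1 stood at -0.90 ± 0.10 and Ald at -0.88 ± 0.12. Heat shock genes fell in 6 of 15 (6 adjusted over the list alone, camera adjusted p = 0.0283, adjusted p = 0.694 with an estimated correlation), but not with fry (0.0602) or without the 2 clusters of mixed content and the ejaculatory bulb-like class (0.0504). Among them was Hsp23 (-0.69 ± 0.21), which lost its call without day 11 replicates 1 and 2 (-0.23).

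The other 14 lists were not called by age. Vitelline membrane and chorion genes were higher in 6 of 20 (5 adjusted over the list alone). The chorion gene Cp15 went from 23.6 ± 18.8 to 270 ± 304 CPM. Cp16 (2.59 ± 0.85) and Cp18 (2.48 ± 0.65) lost their calls without day 11 replicates 3 to 6 (3.57 and 2.92). Cp16 also lost it without replicates 1 and 2 (2.29). Female germline genes were lower in 12 of 35 and higher in 4 (11 and 4 adjusted over the list alone), with the germline helicase gene vas at -1.71 ± 0.20 and aret, a translational repressor gene, at -1.36 ± 0.19. Cell cycle genes were higher in 5 of 27 and lower in 1 (5 and 0 adjusted over the list alone), with CycB3 at 2.05 ± 0.35 and dup, a replication licensing factor gene, at 1.02 ± 0.19. Immediate early and JNK genes went both ways, 7 of 13 lower and 3 higher (8 and 3 adjusted over the list alone). The cell death genes rpr (49.1 ± 16.3 against 15.1 ± 2.5 CPM) and hid (55.1 ± 11.5 against 22.1 ± 2.4 CPM) were higher. The matrix protease gene Mmp1 was lower (-1.37 ± 0.22), but not without replicates 3 to 6 (-0.20). Neuropeptides were lower in 11 of 39 and higher in 3 (11 and 2 adjusted over the list alone), and Nplp3 went from 1075 ± 201 to 95.0 ± 37.9 CPM. Flight muscle genes were lower in 8 of 23 and higher in 5 (8 and 5 adjusted over the list alone). Act79B, an actin gene, lost its call without replicates 3 to 6 (-3.97 ± 0.64 with them, -0.44 without). Ecdysone response genes were higher in 7 of 22 and lower in 5, juvenile hormone genes lower in 4 of 12, lipid and hydrocarbon synthesis genes lower in 4 of 19 and higher in 2 (7, 5, 4, 3 and 2 adjusted over the list alone). Cytosolic ribosomal protein genes were lower in 5 of 91 and higher in 1 (2 and 0 adjusted over the list alone). That list was called lower without day 11 replicates 3 to 6 (adjusted p = 0.00227) and higher without the 2 mixed clusters and the ejaculatory bulb-like class (0.0278), where flight muscle genes were also called, lower (0.0278). With the replicate block, vitelline membrane and chorion genes were called higher (0.0248) and female germline genes lower (0.000316). The sex check list was higher in 3 of 10 and lower in 1, and the housekeeping list higher in 1 of 9 and lower in 1, unchanged in number adjusted over the list alone. None of the 3 yolk protein genes or 6 core histone genes was called by edgeR in either way, over all genes or adjusted over the list alone.

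**Figure D2:**
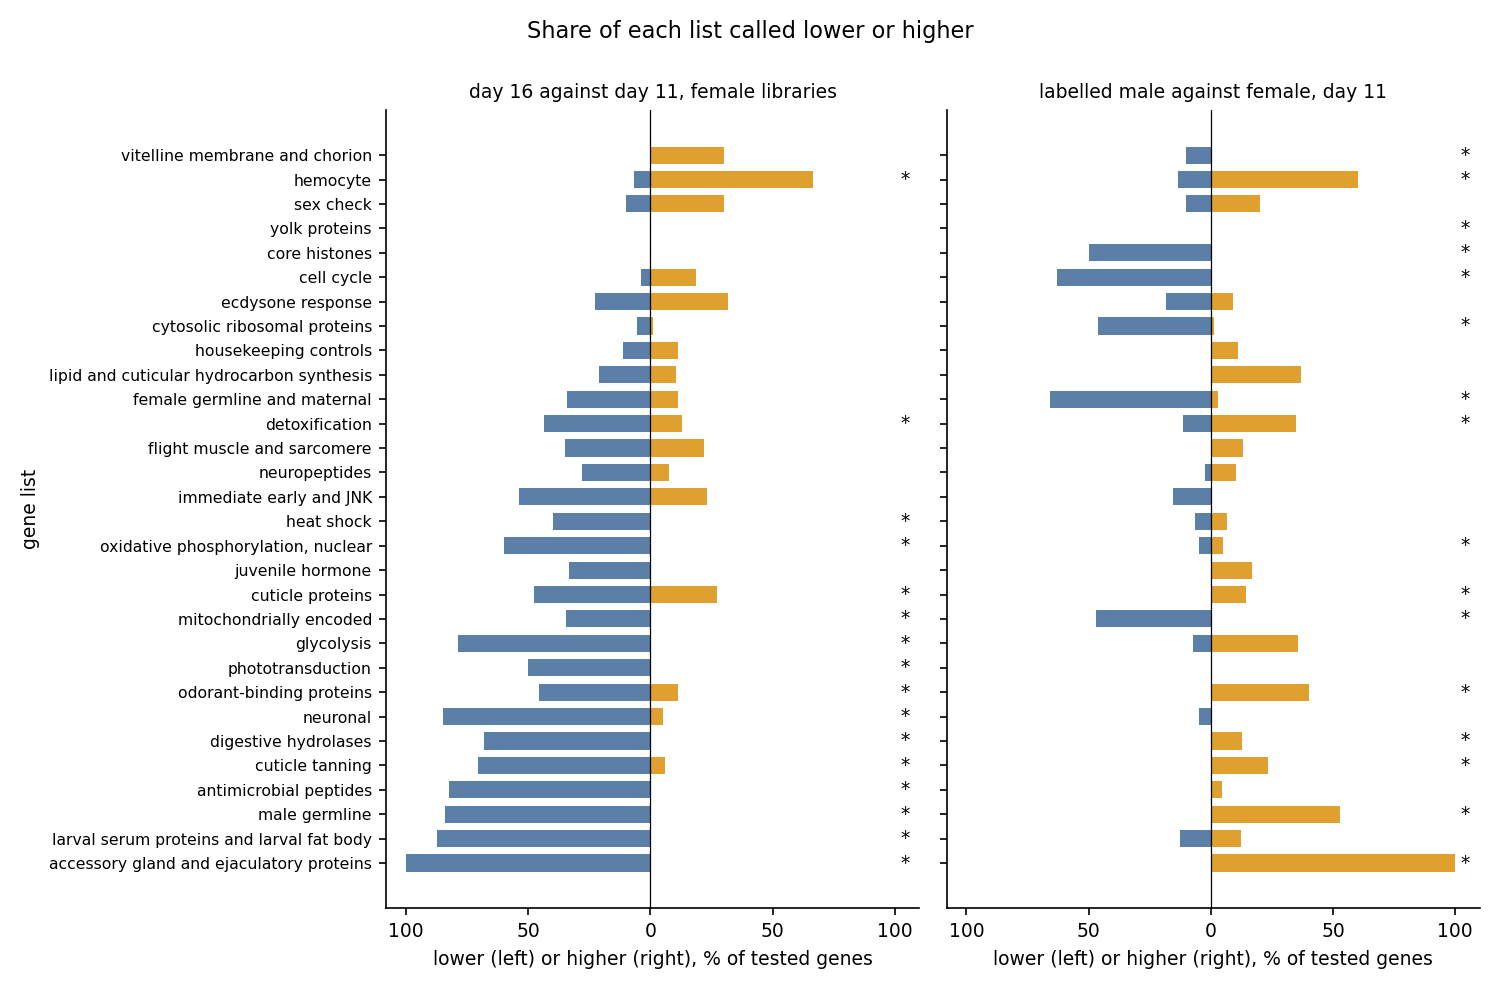
Share of the tested genes of each of the 30 lists (y axis) that edgeR called lower (left) or higher (right), in percent of tested genes, for day 16 against day 11 female libraries and for libraries labelled male against female at day 11. Asterisks mark lists called by camera with its preset correlation, 16 in each panel.

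Within cell classes, the same comparison was made on counts summed per library and class. Malpighian tubule-like cells at day 11 expressed metallothionein genes, whose products bind heavy metals, far above day 16. MtnC stood at 2174 ± 1378 against 64.1 ± 40.6 CPM and MtnE at 1161 ± 647 against 17.9 ± 26.2 CPM (n = 6 and n = 7 libraries). MtnB and MtnD stood at 426 ± 173 and 576 ± 279 CPM at day 11. At day 16 they stood at 7.89 ± 10.37 and 1.93 ± 5.11 CPM, from 1 to 3 counts. MtnB and MtnC were called lower in 6 and 5 classes, so their fall was not particular to Malpighian tubule-like cells. Hemocyte-like cells expressed Ilp4, an insulin-like peptide gene, at 157 ± 42 CPM at day 16 and at no count at day 11 (at least 150-fold higher), and sn, the actin-bundling fascin gene, at 302 ± 80 against 26.0 ± 10.3 CPM. In the same class ninaD, a scavenger receptor gene of carotenoid uptake, went from 623 ± 167 to 48.4 ± 14.6 CPM. There dnd went from 339 ± 153 to 4.45 ± 3.92 CPM and CG9686 from 1979 ± 959 to 9.43 ± 7.20 CPM. CG9686 was called lower in 6 classes. In photoreceptor-like cells rdgA, the diacylglycerol kinase gene of phototransduction, went from 1924 ± 488 to 347 ± 142 CPM.

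Further genes were called in these and other classes. Cyp6d5 and Smvt, a vitamin transporter gene, were higher in Malpighian tubule-like cells (3.31 ± 0.49 and 1.21 ± 0.23), and Vha14-1, a proton pump subunit gene, was lower (-1.77 ± 0.24). Pdh, photoreceptor dehydrogenase, was higher in photoreceptor-like cells (1.43 ± 0.33). Neuron-like cells held more of the neuronal precursor factor gene nerfin-1 at day 16 (39.2 ± 19.6 against 0.565 ± 0.726 CPM) and of Nrt, a cell adhesion gene (71.4 ± 9.8 against 29.9 ± 2.6 CPM). The rise of nerfin-1 was not particular to them, as vitelline membrane follicle cell-like cells held it at 9.16 ± 6.11 CPM against no count (at least 20.5-fold higher). The embryonic patterning gene sna also stood higher in neuron-like cells, at 11.0 ± 4.7 CPM against 0.0998 ± 0.2446 CPM, from 1 count, at day 11. The lin-28 gene was higher in hemocyte-like (6.39 ± 0.42), enterocyte-like (4.92 ± 0.42) and neuron-like cells (3.49 ± 0.35), at 2.17, 1.49 and 0.653 times its whole-library CPM at day 16. Tom was higher in enterocyte-like cells (28.1 ± 12.4 against 0.664 ± 0.870 CPM), at 0.409 times its whole-library CPM. Whether cells like the sub-clusters all but absent at day 11, or their RNA, entered these classes was not tested. Rises within a class, those of Ilp4 and sn included, thus need not be changes of the same cells with age. In enterocyte-like cells wun2, a lipid phosphatase gene, was higher (2.05 ± 0.22). In enteroendocrine-like cells mt:CoI and mt:CoIII were lower (-1.07 ± 0.20 and -1.18 ± 0.17). In epidermis-like cells ple was lower (34.3 ± 52.3 against 2492 ± 1594 CPM) and Cyp4g15 higher (686 ± 556 against 30.5 ± 25.7 CPM). The class held only 182 cells of 5 libraries at day 16, with the rhodopsin gene ninaE at 769 ± 283 CPM against 72.5 ± 58.1 CPM at day 11. There 9 of the 10 genes that lead the class were lower, so its name is in doubt at day 16.

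**Figure D3:**
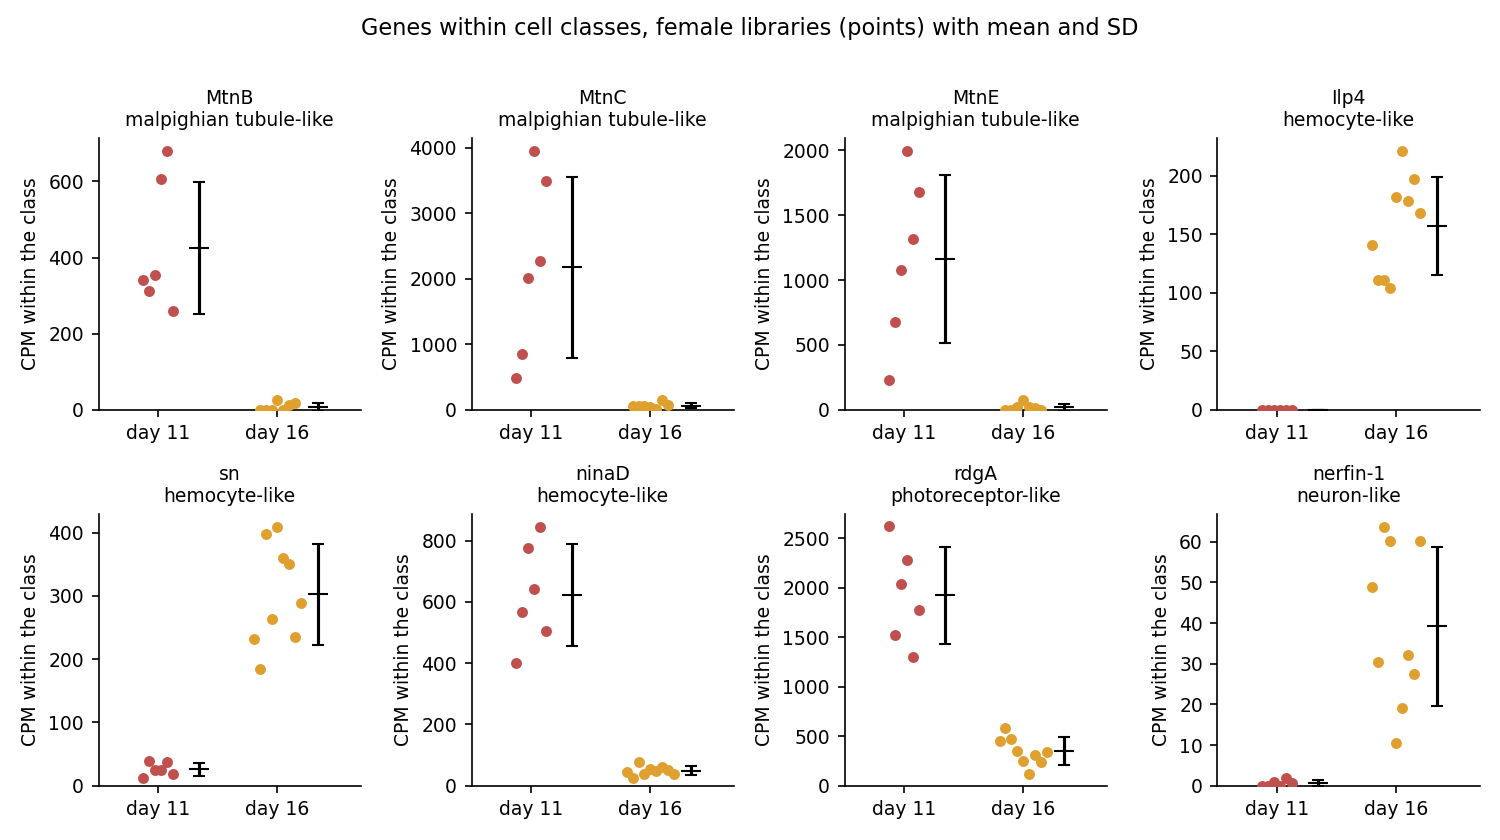
CPM within a cell class for 8 genes in the day 11 and day 16 female libraries, with 1 point per library and, in black, the mean and SD. Day 11 libraries lie above day 16 for MtnB, MtnC and MtnE in Malpighian tubule-like cells, ninaD in hemocyte-like cells and rdgA in photoreceptor-like cells, and below for Ilp4, sn and nerfin-1.

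Summed over the 9 classes tested, 3086 gene and class pairs were higher and 4535 lower at day 16. The counts higher and lower were 978 and 1358 in neuron-like, 860 and 1036 in enterocyte-like, 633 and 834 in hemocyte-like, 373 and 650 in vitelline membrane follicle cell-like, 81 and 342 in epidermis-like, 84 and 136 in photoreceptor-like, 77 and 162 in Malpighian tubule-like, 0 and 16 in enteroendocrine-like and 0 and 1 in chorion follicle cell-like cells. In the last class, with 3 libraries at day 11, edgeR's single call was CG7203, as many calls came from 4 of 25 splits of the female libraries, 283 genes had an unadjusted p under 0.05, and DESeq2 called 1 higher and 16 lower. Enteroendocrine-like cells had 158 such genes, and DESeq2 called 7 higher there. The enterocyte-like class joined 2 clusters, the larger with 74.3% of its cells at day 11 and 65.0% at day 16, so its calls also carry that shift. Of the genes that lead a class, 14 of 20 were lower in neuron-like and 8 of 20 in enterocyte-like cells at day 16. Genes called lower in many classes included Nplp3, Cpr100A and CG7203, in 7, 6 and 9 classes. Where they were among the 5 lower genes of smallest p in a class, they stood at 0.162 to 0.538 times their whole-library level at day 11. That range does not cover the other classes in which they were called, such as the epidermis-like class for CG7203. MtnB to MtnE, ninaD and rdgA stood at 12.7 to 66.4 times the whole-library level in the class given for them above. MtnB and MtnC were called lower in many classes too, at medians of 6.10 and 0.376 times the whole-library level over those classes. Without day 11 replicates 3 to 6 the sums were 622 higher and 1218 lower, and the calls for Cyp6d5 (3.14), Smvt (0.92), Pdh (1.63), mt:CoI (-0.98) and mt:CoIII (-1.22) ended.

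Sizes of cell classes were compared only where no leading gene of the class was called by age, or after clustering again without 7775 genes called by age. The first held for chorion follicle cell-like and enteroendocrine-like cells. The fits for these had only 120 and 126 cells at day 11, in 3 and 5 libraries. A difference of their leading genes could thus have been missed. Chorion follicle cell-like barcodes made up 1.16% ± 0.87 at day 16 and 0.275% ± 0.170 at day 11 (exact permutation test over all splits, two-sided, adjusted p = 0.0305 over 11 classes). This call ended without any one of day 11 replicates 2, 3, 4, 5 or 6 (difference 0.861 to 0.909 percentage points) and without all of replicates 3 to 6 (0.695). Enterocyte-like barcodes, clustered without those genes, made up 1.47% ± 0.63 at day 16 and 2.54% ± 0.87 at day 11 (exact permutation test, adjusted p = 0.0450 over 6 classes). That call ended without any one of day 11 replicates 1, 2 or 3 or day 16 replicates 1, 2, 3, 5, 6, 7 or 9 (difference -1.12 to -0.800). Differences did not pass for neuron-like (6.57% against 9.47%), hemocyte-like (2.28% against 2.53%), vitelline membrane follicle cell-like (4.97% against 2.49%), female germline-like (1.40% against 2.06%) and enteroendocrine-like barcodes (0.244% against 0.227%). Without day 11 replicate 1 or 4 the neuron-like difference passed (-3.65 and -3.62 points). The sixth class of that clustering was named by accessory gland markers, which were all but absent at day 16, with Mst57Db, a leading gene of the class, at 1 count over 9 libraries. The name thus does not hold at day 16, and the size of that class, though it passed (exact permutation test, adjusted p = 0.0300), is not read as that of a tissue. Its call ended without day 11 replicate 3 (-8.37 points) and without all of replicates 3 to 6 (-0.0143). Unnamed clusters held 57.9% of barcodes at day 11, 50.6% in the male libraries and 68.9% at day 16, a share set by naming thresholds chosen after the data were seen.

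The second comparison asks how the libraries labelled male differed from those labelled female at day 11. The libraries labelled male held far more transcripts of the male reproductive tract, such as Acp54A1 (2026 ± 2194 against 7.45 ± 6.72 CPM) and Spn77Bb, a serpin gene (771 ± 654 against 11.7 ± 7.5 CPM). Both male dosage compensation RNAs were higher, roX1 at 500 ± 229 against 41.9 ± 30.8 CPM and roX2 at 76.5 ± 32.6 against 9.64 ± 7.15 CPM. Transcripts of the ovary were lower, such as dhd, a germline thioredoxin gene (17.1 ± 17.4 against 102 ± 27 CPM), and Sxl, the female sex determination gene, stood at 75.2 ± 46.0 against 157 ± 18 CPM. Hml, the hemolectin gene of blood cells, was higher at 156 ± 125 against 31.4 ± 3.9 CPM, with 244 CPM in the library labelled male, replicate 7, and 68.3 CPM in replicate 8. Hemocyte-like barcodes made up 7.48% ± 5.49 against 2.79% ± 1.57 (exact permutation test, adjusted p = 0.393). With 2 male libraries no class alone could pass that test.

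By edgeR, 1762 genes were higher and 1711 lower in the libraries labelled male. With library totals in place of TMM factors, which moved the median of all genes by 0.35 on the log2 scale, 2382 were higher and 480 lower, so directions here are relative to that shift. The counts rest on few libraries: they were 67 and 4 without the library labelled male, replicate 7, and 2244 and 2830 without replicate 8. The number lower was 1018 without female replicate 1 and 1120 without female replicate 2. Without female replicates 3 to 6 they were 2755 and 1576.

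Of the 8 lists higher in the libraries labelled male, the accessory gland and ejaculatory list had 24 of 24 genes higher (24 adjusted over the list alone, median 4.81, camera adjusted p = 2.32e-10, adjusted p = 0.4932 with an estimated correlation). Acp36DE and Acp26Aa stood at 5.28 ± 0.99 and 5.27 ± 0.91. Male germline genes were higher in 10 of 19 (14 adjusted over the list alone, camera adjusted p = 2.2e-05, adjusted p = 0.4932 with an estimated correlation). The germline gene ocn stood at 3.15 ± 0.84 and Mst77F, a sperm chromatin protein gene, at 2.79 ± 0.75. Odorant-binding proteins were higher in 14 of 35 (15 adjusted over the list alone, camera adjusted p = 2.2e-05, adjusted p = 0.4932 with an estimated correlation). Obp51a stood at 5.12 ± 0.70. Hemocyte genes were higher in 9 of 15 and lower in 2 (9 and 3 adjusted over the list alone, camera adjusted p = 0.00211, adjusted p = 0.4932 with an estimated correlation), but not without female replicates 3 to 6 (0.233). Besides Hml, the matrix protein gene Ppn stood at 2.08 ± 0.28 and Sr-CI at 1.97 ± 0.21.

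Cuticle proteins were higher in 12 of 84 (10 adjusted over the list alone, camera adjusted p = 0.00126, adjusted p = 0.499 with an estimated correlation), but not without TMM factors (0.0859). Cpr92F stood at 3.38 ± 0.47. Cuticle tanning genes were higher in 4 of 17 (7 adjusted over the list alone, camera adjusted p = 0.00109, adjusted p = 0.499 with an estimated correlation). Among them was yellow (y) at 2.89 ± 0.46. Detoxification genes were higher in 24 of 69 and lower in 8 (26 and 8 adjusted over the list alone, camera adjusted p = 0.0182, adjusted p = 0.614 with an estimated correlation), but not with fry (0.0742) or without female replicates 3 to 6 (0.0524). Ugt35b, a glycosyltransferase gene, stood at 2.20 ± 0.44 and GstD2, a glutathione transferase gene, at -1.62 ± 0.41. Digestive hydrolases were higher in 6 of 47 (3 adjusted over the list alone, camera adjusted p = 0.0388, adjusted p = 0.650 with an estimated correlation), but not without TMM factors (0.167), with fry (0.198) or without female replicates 3 to 6 (0.647). Mal-A3 stood at 2.04 ± 0.32.

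Of 8 lower lists, cytosolic ribosomal proteins had 42 of 91 genes lower and 1 higher (71 and 2 adjusted over the list alone, median -1.10, camera adjusted p = 1.46e-15, adjusted p = 0.4932 with an estimated correlation). RpS5b stood at -1.52 ± 0.55 and RpS15Ab at -1.43 ± 0.34, and RpS5b lost its call without any one of female replicates 1, 2, 3, 4 or 6 (-1.57 to -1.34). Ribosomal protein genes took 13.1% of UMIs in the library labelled male, replicate 7, 33.3% in replicate 8 and 32.6% to 45.9% in the day 11 female libraries. Female germline genes were lower in 23 of 35 and higher in 1 (27 and 1 adjusted over the list alone, median -1.40, camera adjusted p = 6.47e-11, adjusted p = 0.4932 with an estimated correlation). The germ cell gene pgc stood at -2.18 ± 0.55 and vas at -1.84 ± 0.36. Cell cycle genes were lower in 17 of 27 (22 adjusted over the list alone, median -1.03, camera adjusted p = 1.93e-09, adjusted p = 0.4932 with an estimated correlation). CycA stood at -1.63 ± 0.39 and Mcm6 at -1.49 ± 0.35. Core histones were lower in 3 of 6 (4 adjusted over the list alone, camera adjusted p = 0.0182, adjusted p = 0.4932 with an estimated correlation), but not without female replicates 3 to 6 (0.0524). His2Av stood at -1.49 ± 0.33.

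Mitochondrially encoded genes were lower in 15 of 32 (16 adjusted over the list alone, median -1.37, camera adjusted p = 1.76e-07, adjusted p = 0.4932 with an estimated correlation). The ribosomal RNA mt:srRNA stood at -2.07 ± 0.43. Nuclear oxidative phosphorylation genes were lower in 4 of 80 and higher in 4 (0 and 0 adjusted over the list alone, camera adjusted p = 0.0390, adjusted p = 0.777 with an estimated correlation), but not without TMM factors (0.212) or with fry (0.303). Vitelline membrane and chorion genes were lower in 2 of 20 (2 adjusted over the list alone, median -2.04, camera adjusted p = 5.16e-06, adjusted p = 0.4932 with an estimated correlation). Of the 3 yolk protein genes none passed edgeR's test, also adjusted over the list alone, and the list did (median -1.49, camera adjusted p = 0.0395, adjusted p = 0.499 with an estimated correlation), but not without female replicates 3 to 6 (0.0582). Of 36 genes named for sex and rerun, 30 lost their call without the library labelled male, replicate 7. Among them were roX1 (3.01), roX2 (2.46), Sxl (-0.54), Acp26Aa (1.35), Acp36DE (1.48), ocn (1.93), Mst77F (1.64), dhd (-1.79), vas (-1.45), pgc (-1.39), Ppn (0.95), Cpr92F (1.77), mt:srRNA (-1.77) and His2Av (-0.90). Without replicate 8 all of them but Fcp3C kept theirs.

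The other 14 lists were not called by sex. Lipid and hydrocarbon synthesis genes were higher in 7 of 19 (7 higher and 1 lower adjusted over the list alone), with the lipid droplet gene Lsd-1 at 1.27 ± 0.16, glycolysis genes in 5 of 14 with 1 lower (6 and 1 adjusted over the list alone). Neuropeptides were higher in 4 of 39 with 1 lower (3 and 0 adjusted over the list alone) and flight muscle genes in 3 of 23 (2 adjusted over the list alone). Juvenile hormone genes were higher in 2 of 12, the sex check list in 2 of 10 with 1 lower and ecdysone response genes in 2 of 22 with 4 lower, with the same counts adjusted over the list alone. Larval serum protein genes had 1 of 8 higher and 1 lower, and housekeeping genes 1 of 9 higher (as many adjusted over the list alone). Antimicrobial peptides had 1 of 23 higher, heat shock genes 1 of 15 higher and 1 lower, neuronal genes 1 of 20 lower, and adjusted over the list alone 0, 0 and 1, and 0. Immediate early genes had 2 of 13 lower (2 adjusted over the list alone). No gene of the 18 for phototransduction was called by edgeR, over all genes or adjusted over the list alone. Without female replicates 3 to 6 the larval serum protein (0.000501) and antimicrobial peptide lists (0.00253) were called higher. Without the 2 mixed clusters and the ejaculatory bulb-like class, glycolysis (0.0117) and neuronal genes (0.0485) were.

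X-linked genes stood lower than autosomal genes in the libraries labelled male by a difference of median fitted log2 fold changes of -0.19 (1036 X-linked and 5376 autosomal genes). Taken from the medians of each library, the difference was -0.26 (exact permutation test over 28 splits, two-sided, p = 0.0357, the smallest this design can give). The fitted difference was -0.08 without the library labelled male, replicate 7, and -0.32 without replicate 8, where the 7 splits cannot give a p under 0.143.

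Within cell classes, transcripts of the male reproductive tract were higher in the libraries labelled male in classes outside that tract as well, and there they stood below their whole-library level. Acp54A1 reached 843 ± 917 CPM in neuron-like and 1110 ± 1354 CPM in hemocyte-like cells, which is 0.416 and 0.548 times its whole-library CPM. The RNA roX1 stood above its whole-library level in photoreceptor-like cells (1362 ± 57 against 56.3 ± 49.5 CPM, 2.72 times the whole-library CPM). In ejaculatory bulb-like cells CG18628 (2915 ± 2474 against 52.4 ± 35.9 CPM) and the esterase gene Est-6 (399 ± 124 against 19.1 ± 18.8 CPM, n = 4 female libraries) were higher, and these too stood below their whole-library level (0.858 and 0.561 times). Over 8 classes 649 gene and class pairs were higher and 544 lower by edgeR, most of them, 352 and 447, in neuron-like cells. That class joined 2 clusters, the larger with 87.8% of its cells in the male and 78.9% in the female libraries, so its calls also carry that shift.

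These sums were 95 and 3 without the library labelled male, replicate 7, and 1607 and 1337 without replicate 8, and 227 pairs were lower without female replicates 3 to 6. The 227 pairs were over 7 classes, since the ejaculatory bulb-like class was not run there, against 543 over the same classes with all libraries. No class size passed by sex. By the exact permutation test 0 of 11 classes passed, with 1 unadjusted p under 0.05. By edgeR on cell counts 0 passed, with 2 unadjusted p under 0.05. The smallest p by the exact test was that of ejaculatory bulb-like barcodes (3.62% ± 0.30 against 0.345% ± 0.282, exact permutation p = 0.0357, the smallest this design can give, adjusted p = 0.393). A class alone at that p cannot pass over 11 classes, so the exact test cannot show that class sizes were alike.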

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

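Tests chosen after the result was seen were those of free RNA, of both roX RNAs, of swapped labels, of maternal transcripts, of adult male cells, of total counts, of other splits for genes within classes and of splits that keep alike libraries together. In day 11 female replicates 3 to 6, barcodes with 3 or more UMIs of other accessory gland list genes were examined. They held a median of 6.30 times the UMIs of a gene that their total UMIs give. The range was 4.93 to 8.11 by library, and 22 of 24 genes were over 5. This argued against free RNA spread over barcodes in proportion to their UMIs. The measure was 1.10 and 1.98 in the male libraries, and 1.99 in day 11 replicates 1 and 2. A low value thus did not mark the absence of male cells, and the measure cannot decide whether male cells were present. Barcodes carried over from the male libraries were argued against as well, since the 688 barcodes of male-like clusters recurred there at 0.772 times the rate of others (2.62% and 3.39%), and so was a swap with the 2 male libraries, since roX1 reached at most 0.199 times their lower level (74.6 and 376 CPM). Male cells among the input could not be decided by the test of roX1 planned beforehand, with 1.85 times as many neuron-like barcodes with 3 or more UMIs as a Poisson spread gives (379 and 205.1). That value met the bound set beforehand against male cells, but a mixture at the rate of the male library would itself have given 1.43, so the bound was wrong. The later test of both roX RNAs gave 3.26 (1.03 and 1.24 in the male libraries), so male cells, or male flies, in these libraries may be the source.

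Day 16 libraries held 4218 barcodes in sub-clusters that had 4 in the female and 1 in the male libraries of day 11. The sub-clusters were picked for being all but absent at day 11, so these counts test nothing. Zygotic patterning genes of the embryo stood there at a median log2 fold of 2.79 (SD 1.18) over the other day 16 barcodes, with 35 of 40 genes over 1. Maternal transcripts of the ovary were argued against, since roX1 was 12.2 times as high there (562 and 46.0 CPM). These sub-clusters held 37.7% of the roX1 UMIs of day 16, so they do not account for all of them. Among day 16 neuron-like barcodes, 109 had 3 or more roX1 UMIs, against 11.0 from a Poisson spread. The source of that roX1 was not tested. At day 16 the accessory gland list per roX1 UMI had a median of 0.00147 times that of day 11 replicates 3 to 6. With 21 of 24 genes under 0.1, this argued against adult male cells as at day 11 for most of these genes. A pooled ratio seen first, 0.108, lay on the other side of the bound of 0.1. The measure was changed after that ratio was seen, so adult male cells were not excluded. Embryos may be the source of these cells, with a difference of adult tissue by age left untested.

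Cuticle genes fell within several classes besides the epidermis-like one. The 7 cuticle protein genes called lower in at least 5 classes stood in day 11 classes at a median of 0.263 times their whole-library level (0.250 to 0.314). Free RNA could be the source. Genes expressed mainly in another class would stand below that level without free RNA too, so the ratio cannot decide. All 127 genes called so had a median of 0.405 (quartiles 0.265 and 0.959). The number of genes lower in whole libraries was 1.16 times that after thinning to 1 total. Counts within classes were not thinned, so this cannot decide on a difference in total counts for the falls within classes. A difference of the cells by age stays open and untested.

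Of 100 splits of the 15 female libraries into 6 and 9, 1, the real one, gave as many genes by age (6467, with 1934 the highest other), so chance can be excluded for the count of genes only if the libraries varied independently. For lists 14 of 100 gave as many (16, with 20 the highest other), so it cannot be excluded there. Within classes 1 of 25 gave as many calls (7621, with 50 the highest other), so under the same condition chance can be excluded for the sum, but not for chorion follicle cell-like cells alone (4 of 25). Day 16 libraries 1 and 2, 3 and 4, 5 and 6, and 9 and 10 stood in alike pairs (chi-square per degree of freedom 9.43 to 32.2 in them and 31.6 to 164 between others), and day 11 libraries in sets of 1 and 2 and 3 to 6. The 15 splits that keep such sets whole are too few for a share under 0.05. Of these, 1 of 15, the real one, gave as many genes (6467, with 2187 the highest other). The same held for calls summed over classes (7621, with 1576 the highest other). Taken alone, epidermis-like cells had as many calls in 2 of 15 (423, with 423 the highest other). Chorion follicle cell-like cells had as many in 6 of 15, and each other class in 1 of 15.

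Of 188 sets of libraries tested for a library far from its group, 19 had one, and chance gives about 1 in 20. Each value here is the gap to the nearest library over the range of the group. Day 11 female replicate 3 stood highest in total UMIs (0.752), median UMIs (0.631) and median genes (0.729) per barcode, Cp16 (0.749, 17.2 CPM), Cp18 (0.868, 35.9 CPM) and CycA (0.676, 57.7 CPM). Day 16 replicate 7 stood highest in roX1 (0.647, 186 CPM), CycB3 (0.535, 44.1 CPM) and dup (0.495, 48.0 CPM) and lowest in Ald (0.601, 138 CPM). Day 16 replicate 10 stood highest in Cp15 (0.595, 1006 CPM), Cp16 (0.545, 135 CPM), Cp18 (0.593, 274 CPM) and Dup99B (0.507, 0.101 CPM). Of the other day 16 libraries, replicate 9 stood highest in barcodes (0.5, 30000), replicate 5 in Mst57Db (1.0, 0.0497 CPM), replicate 2 in Ebp (0.629) and Act79B (0.778, 3.75 CPM) and replicate 1 in Acp1 (0.609).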

How the results depend on the processing

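Alternatives chosen after seeing the data were those without day 11 female replicates 3 to 6, replicates 1 and 2 or the split clusters, without the highest Scrublet scores, and clustering without age genes. The cause of the changes here was not tested. Without replicates 3 to 6 the genes by age were 1749 higher and 1664 lower, and the genes by sex 2755 higher. The lists higher by age were then 0, and DptB turned (0.69). The sums within classes were 622 higher and 1218 lower by age, and 227 lower by sex over 7 classes. Counts of genes by sex were 796 and 179 with only the 2 groups in the fit, 480 lower without TMM factors, 1116 lower after thinning, 912 lower without replicates 1 and 2, 3480 and 2615 without replicates 3 to 6 and male replicate 8, and 1137 lower without the split clusters. Within classes by sex, 1861 were higher with no filter on low counts. Leaving out 1 library gave 2670 to 2961 higher and 3246 to 3430 lower genes by age, and 67 to 2244 higher and 4 to 2830 lower by sex. It gave 95 to 1607 higher and 3 to 1337 lower within classes by sex, and -0.318 to -0.0848 for X against autosomes. The range for X against autosomes is of differences of mean log2 CPM, taken without a new fit. In the fits a lone male library was assumed to vary like the other groups.

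With an estimated correlation 0 lists were called in either direction, by age or sex. Lists higher by age were 2 with fry, 3 without TMM factors, 2 with the replicate block and 2 without the split clusters. The replicate block, on libraries 1 to 6 of both ages, gave 2360 higher and 2458 lower genes (2529 and 2678 unblocked) and 1491 and 2260 within classes. Deviations correlated at -0.0404 to 0.0654 within a number, and 0 of 6 libraries correlated best with their own number, so the numbers are no sign of pairing.

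Share differences (percentage points) by leaving out 1 library, then without replicates 3 to 6 and with the block, were as follows. Chorion follicle cell-like 0.694 to 1.002, 0.695 and 0.383, enterocyte-like as clustered without age genes -1.27 to -0.800, -2.10 and -1.22, and accessory gland-like -11.1 to -5.79, -0.0143 and -9.22. Hemocyte-like, -0.536 to 0.131, turned without day 11 replicates 3 (0.113) and 4 (0.131), without 3 to 6 (1.03) and with the block (0.0613). Neuron-like, -3.65 to -1.93, passed with all variable genes (-4.56), and female germline-like, -0.838 to -0.236, with 500 UMIs (-1.27), and turned without 3 to 6 (0.219). Enteroendocrine-like, -0.00832 to 0.0417, turned without day 11 replicate 1.

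Of the named genes' values under other settings, 601 by age kept direction and call and 9 lost the call, and 356 and 38 did by sex. Of lists 85 and 27 did by age and 53 and 27 by sex. Within classes by sex, 14 values lost the call and 30 kept it with 1 male library left out, and 12 and 79 did otherwise. Those lost include MtnD, MtnE and Acp54A1 in Malpighian tubule-like and roX1, Nplp3 and EbpII in enteroendocrine-like cells, but none of the pairs of gene and class given in the text. Not run were 10 combinations of a class with fewer barcodes or libraries, resolution 0.5 for classes absent there, and removal by Scrublet's own threshold. Of the counts of whole-library genes, thinning to the smallest total moved only that lower by sex past 1.5 times. With 2 male libraries, the fit by sex found 34% and 38% of simulated 2-fold changes, in genes of at least 10 CPM and libraries simulated as independent.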
